A study of Homo sapiens with 6 samples.

How the data were processed

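The series holds 6 arrays of A498 cells, 3 infected with a control hairpin lentivirus (shCtrl) and 3 with an MCM8 hairpin lentivirus (shMCM8), with 20 µL of virus per well per the labels' protocols. Total RNA (6 µg per the labels' protocols) was labelled with biotin and hybridized to Affymetrix PrimeView arrays, 1 colour, and scanned on an Affymetrix scanner per the series' design text. The deposited values are log2 intensities, 1 per probe set and array, normalized between arrays by the authors before deposit. The normalization method, background correction, summarization software and genome build of the annotation were not given in the sources used here. The other deposited matrix of the same arrays held identical values (largest absolute difference 0). The groups were taken from the labels.

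Of 49395 probe sets, 102 were controls, 430 had no gene symbol, 1994 had several symbols and 46869 had 1. A gene was represented by the probe set with the highest mean over the 6 arrays, which gave 18837 genes, and no filter on low values was used. The deposited gene symbols were updated through the Entrez gene ID to the RefSeq gene annotation of GRCh38.p14 (18712 of 18837 genes matched, and 1128 symbols changed). No coordinates of that assembly were used: 15.5% of the annotated alignments overlapped the same gene in it, so the deposited positions belong to another build. The files used hold no detection calls, and the means of the 23 background probe sets run from 3.33 to 11.85, so they set no single threshold. Whether a dim gene was above background is therefore unknown, and a small change of a dim gene can be understated.

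The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes, group only) with Benjamini-Hochberg adjustment over the genes or probe sets, at an adjusted p under 0.05 and at least 2-fold, the threshold of the series' design text. Named genes followed a rule fixed before the data were examined: MCM8, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups (8 falls existed), up to 3 members past the threshold of each list that passed camera or had 4 such members, members past the threshold of other lists with 3 or fewer of them, and CDKN1A, MCM9, MCM2 to MCM7, CDK1, CCNB1 and CCND1. Symbols of uncharacterised genes were to be left out, and 0 were. Of each called list up to 3 members with a change under 2-fold, the largest with an adjusted p under 0.05, were added, a choice made after seeing the values, as were the proteasome lists. In the text they are named where a list had no member past 2-fold, 2 of them are not reported here, and all remain in the counts over named genes and lists. The 41 gene lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Gene Ontology terms of 10 to 300 genes from the deposited annotation were tested with camera (2700 terms) and with a hypergeometric test against the 14968 genes with a term. The proteasome subunits were also compared with 10000 random lists matched on mean level in 20 bins.

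Alternatives were the replicate number as a block, each array left out in turn, quantile normalization, median centring, a trended and robust variance prior, filters on the lowest 25% and 50% of genes, the mean of all probe sets, the methods' t-test with the same adjustment, a test against a 1.5-fold change, an adjusted p of 0.01, no fold threshold, values below the 20th percentile raised to it, and other set tests. An alternative without _x_at and _s_at probe sets was added after seeing the data. Same-numbered arrays of the 2 groups did not deviate together, so the numbers were not used as pairs.

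The scripts were tested on simulated data for the comparison of shMCM8 against shCtrl, with 18837 genes and 50 changed genes per fold size. At an adjusted p under 0.05 limma found 88% of 1.5-fold changes, with 8 false calls in 18637 unchanged genes. At the full threshold it found 98% of 2.5-fold and 100% of 4-fold and of 8-fold changes, with 1 false call. The methods' t-test found 24% of 1.5-fold and 68% of 2.5-fold changes at an adjusted p under 0.05. Camera found 0 of 40 unchanged lists of 30 independent genes and found the 1 list shifted by 0.2. The simulated genes were independent, so they do not test the preset correlation. Their variances were drawn from limma's fitted prior and were equal in both groups, so the comparison with the t-test favours limma. On the real arrays the median SD of a gene was 0.069 within shCtrl and 0.047 within shMCM8. Plots were drawn with matplotlib 3.10.9.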

Results

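Gene expression was measured on 6 Affymetrix PrimeView arrays, which carry oligonucleotide probe sets for the 3′ part of human transcripts. The RNA came from A498, an established human renal cell carcinoma line, infected with lentivirus carrying a short hairpin RNA. In 3 samples the hairpin was a control (shCtrl) and in 3 it was labelled as directed against MCM8 (shMCM8). MCM8 is a helicase of the minichromosome maintenance family that acts with MCM9 in homologous recombination repair. Each array gave a normalized log2 value for 49395 probe sets, with array medians between 7.28 and 7.36. The number of arrays limits the precision of every value below. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. Pearson correlations across genes were 0.9985 to 0.9991 between arrays of the same group and 0.9962 to 0.9965 between arrays of different groups, and genes are not independent replicates.

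The first comparison was of the targeted gene. MCM8 (Entrez gene 84515) was lower in shMCM8 than in shCtrl on each of its 5 probe sets, which the deposited annotation aligns to the plus strand of chromosome 20, for the brightest probe set from 5931266 to 5975829. The genome build of these positions was not given in the sources used here. On the brightest probe set the normalized log2 intensity was 9.01 ± 0.06 (SD, n = 3) in shCtrl and 8.67 ± 0.14 (SD, n = 3) in shMCM8. The log2 change was −0.34 with an SE of 0.073, which left 79.0% of the shCtrl intensity (limma, adjusted p = 0.0157). Over the 5 probe sets the remaining intensity ranged from 71.7% to 83.4% of shCtrl. All 3 shMCM8 values lay below all 3 shCtrl values, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. In some fits the fall on the brightest probe set did not reach an adjusted p under 0.05. These were limma without shCtrl replicate 2 (0.0570), shMCM8 replicate 1 (0.0592) or shMCM8 replicate 2 (0.0591), and the methods' t-test (0.143). The test against a 1.5-fold change (adjusted p = 1) asks whether a change exceeds 1.5-fold, so this 1.27-fold fall could not pass it. On the probe set level the adjusted p of the 5 probe sets ran from 0.00153 to 0.0169 (limma). The mean of all MCM8 probe sets changed by −0.37 (limma adjusted p = 0.000896). A larger fall than that of MCM8 was measured for 465 of 18837 genes, or 2.47%.

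**Figure D1:**
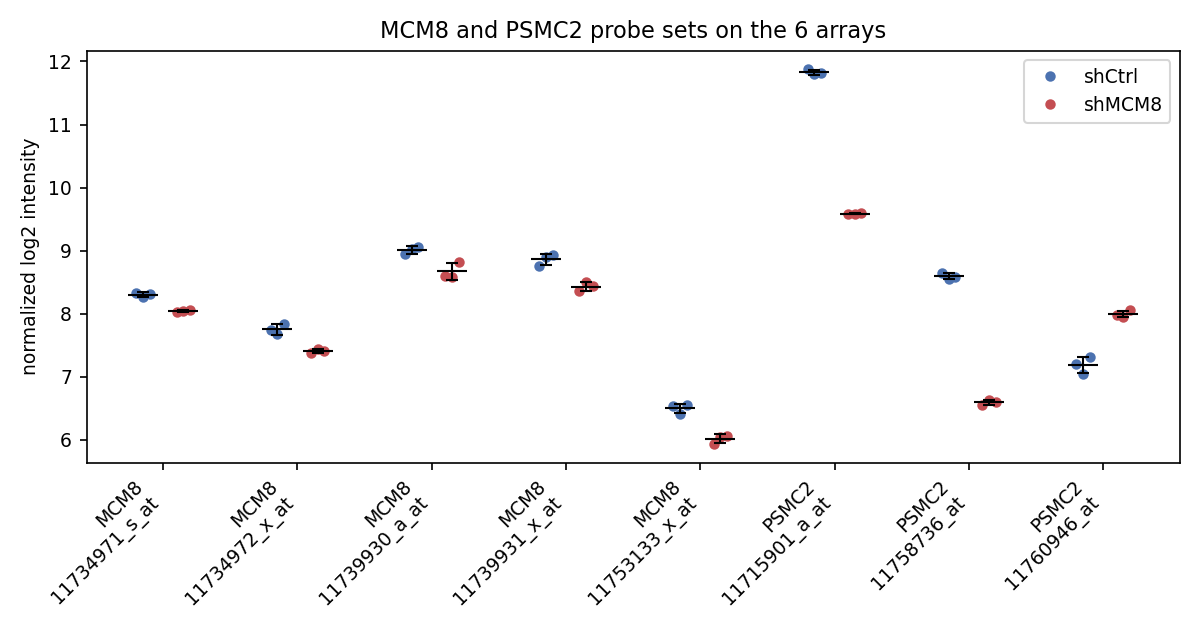
Normalized log2 intensity of the 5 MCM8 and 3 PSMC2 probe sets on the 6 arrays; points are arrays, bars the mean and whiskers the SD of 3 arrays. MCM8 was lower in shMCM8 by 0.26 to 0.48 on the log2 scale, and PSMC2 was lower on 2 probe sets and higher on the third.

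The second comparison asked which genes differed between shMCM8 and shCtrl. At the study's threshold of at least 2-fold and an adjusted p under 0.05, 36 genes were higher and 8 were lower in shMCM8 among 18837 genes. The largest fall was that of PSMC2, an ATPase subunit of the 19S regulatory particle of the proteasome, from 11.83 ± 0.04 (SD, n = 3) to 9.59 ± 0.01 (SD, n = 3), a 4.74-fold decrease (log2 change −2.24, SE 0.036, limma adjusted p = 1.56e-06). OSTM1, a lysosomal membrane protein, changed by −1.46, and VTI1B, a SNARE of endosomal membrane fusion, by −1.40. SOST, which encodes the Wnt antagonist sclerostin, changed by −1.25 and CENPK, a kinetochore protein, by −1.17. PGM2L1, a glucose-1,6-bisphosphate synthase, changed by −1.09, EI24, an endoplasmic reticulum membrane protein, by −1.03, and SUCLG2, a subunit of succinyl-CoA ligase, by −1.001. The largest rise was that of MLLT11, from 9.34 ± 0.04 (SD, n = 3) to 11.45 ± 0.03 (SD, n = 3), a 4.31-fold increase (log2 change 2.11, SE 0.039, limma adjusted p = 2.01e-06). PIR, which encodes the iron-binding nuclear protein pirin, changed by 1.92, FAM241B by 1.78 and the diacylglycerol kinase gene DGKG by 1.76. NDRG4 changed by 1.56 and GCNT3, a glycosyltransferase of mucin-type glycans, by 1.55. AKR1C3, an aldo-keto reductase, changed by 1.36, the complement protease gene C1S by 1.33 and FBXO2, an F-box protein that binds N-glycans, by 1.32. UNKL changed by 1.32, GLA, the lysosomal alpha-galactosidase A, by 1.29 and CAPS2 by 1.28. In all 44 genes the 3 arrays of each group did not overlap, which was so for 38.1% of all genes, against 10% by chance. Genes past the threshold are likely to show this, so it adds no support to their calls.

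**Figure D2:**
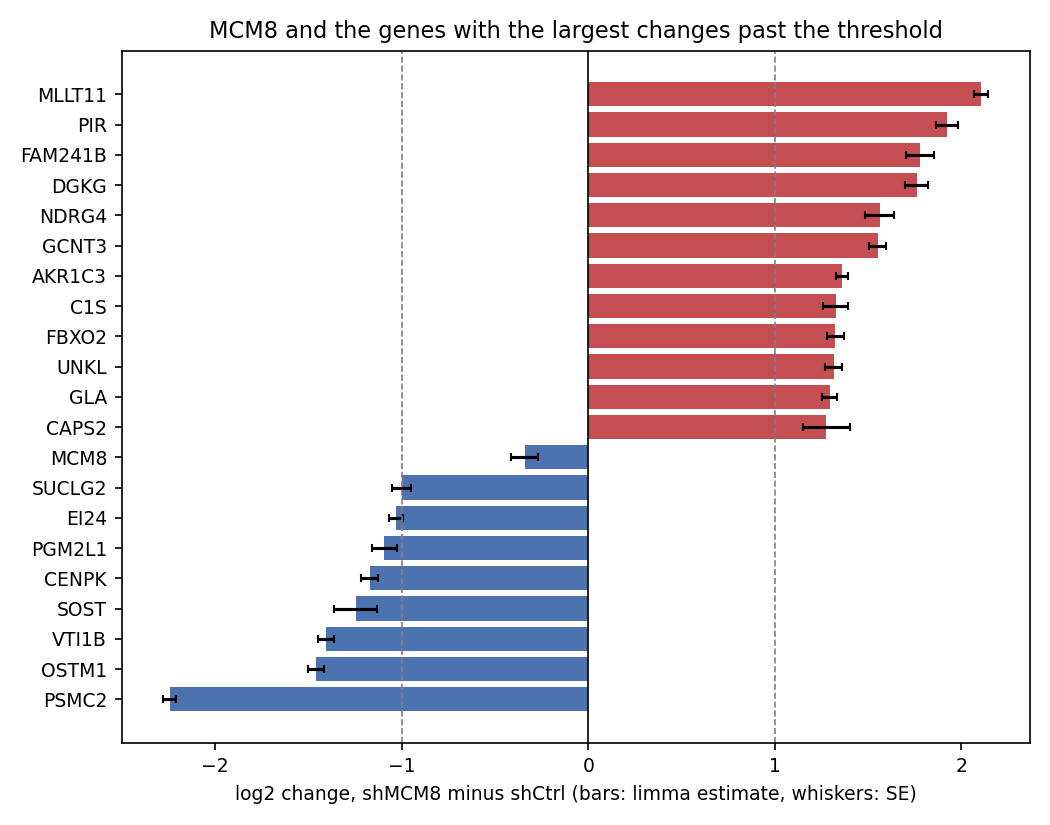
Log2 change, shMCM8 minus shCtrl, of MCM8 and of the 12 largest rises and 8 largest falls past the threshold; bars are the limma estimate from 3 arrays per group and whiskers its SE, with dashed lines at a 2-fold change. PSMC2 had the largest fall (−2.24) and MLLT11 the largest rise (2.11), and MCM8 changed by −0.34.

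The 44 genes came from limma's moderated test with Benjamini-Hochberg adjustment, and 4139 genes had an adjusted p under 0.05 at any fold, 1900 higher and 2239 lower. The latter count was 2648 without shMCM8 replicate 3, 2716 without shMCM8 replicate 2 and 1957 in the methods' t-test. Averaging all probe sets of a gene called 26 genes, 22 higher and 4 lower, of which 23 were among the 44, and gave log2 changes of −1.14 for PSMC2, 0.78 for NDRG4, 0.65 for AKR1C3 and 0.65 for UNKL. With the probe sets of the _x_at and _s_at classes left out, a setting chosen after seeing the data, 41 genes were called, 38 of them among the 44, and NDRG4 changed by 0.06 (limma adjusted p = 0.524) and SUCLG2 by −0.01 (limma adjusted p = 0.967), and CAPS2 did not pass the methods' t-test (adjusted p = 0.0774). Against a 1.5-fold change in limma 63 genes were called, 39 of them among the 44, and CAPS2 (adjusted p = 0.106) and SOST (adjusted p = 0.0919) did not pass. Of the 3 PSMC2 probe sets 2 fell, to 21.1% and 25.01% of the shCtrl intensity, and the third, whose alignment lies within the span of the others, rose by 0.81 (limma adjusted p = 0.000403). On the level of single probe sets, 89 were higher and 23 lower, or 112 of 49293, and 9646 passed the adjusted p at any fold.

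Genes annotated to the proteasome rose as a group in shMCM8. Of 2700 Gene Ontology terms tested with camera, 104 passed an adjusted p of 0.05, 48 of them higher and 56 lower, and the term with the smallest p was the proteasome complex. Among its 64 measured genes 40 rose and 5 fell, with a median log2 change of 0.50 (camera adjusted p = 6.23e-19, unadjusted p = 0.0427 with an estimated correlation). In the proteasome accessory complex 15 of 17 genes rose and 1 fell, with a median of 0.83 (camera adjusted p = 7.18e-14, unadjusted p = 0.0221 with an estimated correlation). With an estimated correlation 0 of the 2700 terms passed (smallest adjusted p = 0.9997). Among the genes past the threshold and higher, 5 belonged to that term, an enrichment over the 14968 genes with a term (hypergeometric adjusted p = 3.74e-07). The subunits past the threshold were chosen after their values were seen, and they were PSMD3 (1.23), PSMD13 (1.19), PSMC4 (1.15), PSMD1 (1.06) and PSMD11 (1.02). Subunits of the 26S proteasome, the main cytosolic protease for ubiquitinated proteins, were then taken as a list chosen after seeing these values. Apart from PSMC2, 30 of 30 measured subunits rose, by 0.38 to 1.23 on the log2 scale, with a median of 0.78 or 1.72-fold (camera p = 6.58e-38, p = 0.0114 with an estimated correlation). All 13 measured subunits of the 20S core, all 12 measured non-ATPase subunits and the other 5 ATPases of the 19S particle were among them. None of the 5 measured subunits of the immunoproteasome and PA28 passed the test (0 of 5, limma, with 1 at an unadjusted p under 0.05), and of 9 assembly factors 1 rose and 3 fell. On the same arrays the hybridization controls were higher in shMCM8 by 0.09 and the poly-A spike-in controls by 0.23 on the log2 scale.

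**Figure D3:**
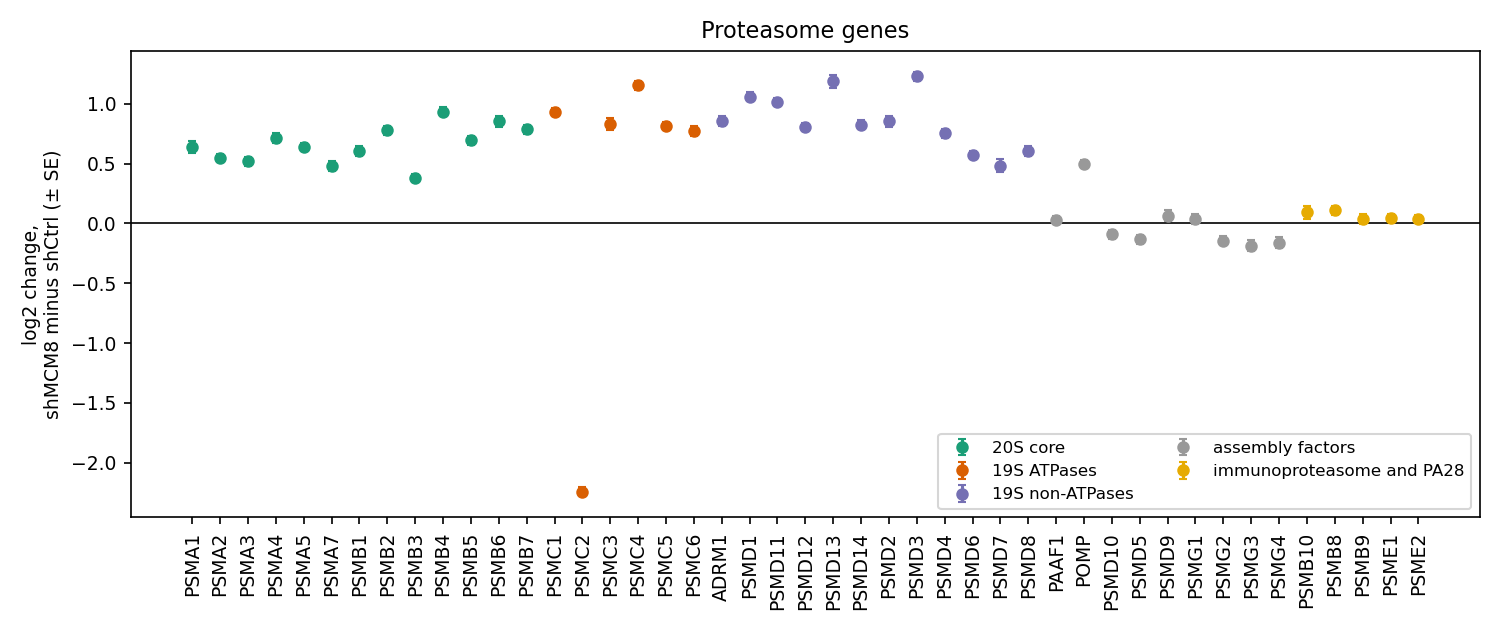
Log2 change, shMCM8 minus shCtrl, of proteasome genes, with the limma SE from 3 arrays per group as whiskers and colours for the class of subunit. The 20S and 19S subunits lay between 0.38 and 1.23, apart from PSMC2 at −2.24.

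The third comparison was of 41 gene lists fixed before the data were examined. By camera with a preset correlation, 5 lists were higher and 12 lower in shMCM8. Members of the called lists with a change under 2-fold were chosen as examples after their values were seen. No list passed with an estimated correlation, when 5 lists had an unadjusted p under 0.05, and 24 lists passed fry, which tests a list's own genes and not the list against other genes, including all 17 called.

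Genes of the NRF2 antioxidant program rose in shMCM8. Of 26 measured targets, 15 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 change of 0.33 (camera adjusted p = 8.38e-12, adjusted p = 0.262 with an estimated correlation). AKR1C3 rose by 1.36, SRXN1, which repairs oxidized peroxiredoxins, by 1.10 and GCLM, a subunit of the enzyme that limits glutathione synthesis, by 1.01. In the list of autophagy and lysosome genes 16 of 33 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 1.03e-06, adjusted p = 0.262 with an estimated correlation). GLA rose by 1.29, the autophagosome protein gene GABARAPL1 by 1.03 and GPNMB, which encodes a lysosomal glycoprotein, by 1.01, the last not past a 1.5-fold change in limma (adjusted p = 0.356). Of 34 interferon-stimulated genes 16 rose and 1 fell (20 and 3 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 2.10e-06, adjusted p = 0.330 with an estimated correlation). BST2 rose by 0.71, IFI44L by 0.44 and IFI44 by 0.35. Of 33 NF-κB targets and cytokines 12 rose and 4 fell (15 and 6 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00146, adjusted p = 0.389 with an estimated correlation). The chemokine gene CXCL1 rose by 0.47 and BIRC3 by 0.41, and the cytokine gene IL11 fell by 0.52. Of 33 respiratory chain subunits 9 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0113, adjusted p = 0.689 with an estimated correlation). SDHC rose by 0.30 and NDUFA6 by 0.24, and NDUFB10 fell by 0.21. SDHC was at 0.09 (limma adjusted p = 0.374) without the _x_at and _s_at probe sets. NDUFB10 lost its call without shMCM8 replicate 2 (limma adjusted p = 0.0757) and without shMCM8 replicate 3 (limma adjusted p = 0.0666), and the respiratory chain list lost its call without shCtrl replicate 1. On the same arrays, poly-A spike-in controls were higher in shMCM8 by 0.23 on the log2 scale.

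Genes of DNA replication and cell division fell in shMCM8. Of 31 genes for replicative polymerases, their cofactors and nucleotide supply, 20 fell and 0 rose (25 and 0 adjusted over the list alone), with a median log2 change of −0.23 (camera adjusted p = 1.50e-09, adjusted p = 0.316 with an estimated correlation). The chromatin regulator gene UHRF1 fell by 0.69 and the dUTPase gene DUT by 0.60. Of 41 genes of G2 and mitosis 23 fell and 0 rose (29 and 1 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 1.07e-08, adjusted p = 0.262 with an estimated correlation). The cyclin gene CCNA2 fell by 0.40, the checkpoint gene MAD2L1 by 0.36 and the kinase gene AURKB by 0.36. Of 33 genes of origin licensing and firing, with MCM8 left out, 19 fell and 2 rose (21 and 3 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 1.06e-05, adjusted p = 0.262 with an estimated correlation). MCM10 fell by 0.65 and GINS2 by 0.49, while the origin recognition gene ORC3 rose by 0.96. Among the other members of the helicase family MCM7 fell by 0.31, MCM3 by 0.30, MCM4 by 0.30, MCM9 by 0.24 and MCM5 by 0.22, whereas MCM2 was at −0.11 (limma adjusted p = 0.107) and MCM6 at 0.08 (limma adjusted p = 0.291). Of 24 regulators of the G1 to S transition 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.000627, adjusted p = 0.262 with an estimated correlation). CCNE2, a cyclin of S phase entry, fell by 0.58, E2F8 by 0.56 and the phosphatase gene CDC25A by 0.48. CDK1 fell by 0.30 and CCNB1 by 0.21, while CCND1 was at −0.13 (limma adjusted p = 0.0516, and 0.0312 without shCtrl replicate 2) and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at −0.03 (limma adjusted p = 0.822). Of 34 homologous recombination genes, the pathway in which MCM8 acts, 11 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of −0.09 (camera adjusted p = 0.00338, adjusted p = 0.262 with an estimated correlation). RMI2 fell by 0.57 and the nuclease gene DNA2 by 0.36, and SWI5 rose by 0.34. In the methods' t-test MCM9, MCM3, MCM5, CDK1, MAD2L1, GINS2, DNA2 and SWI5 did not pass (adjusted p from 0.0584 to 0.0862). On the same arrays the ACTB 3′ minus 5′ difference was higher in shMCM8 by 0.17 on the log2 scale, and the 18S ribosomal RNA controls were lower by 0.24.

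Ribosome biogenesis factors, YAP and TEAD targets and ATF4 and CHOP targets were also lower in shMCM8, and 4 more lists were called lower with medians closer to 0. Of 29 ribosome biogenesis factors 16 fell and 0 rose (18 and 1 adjusted over the list alone), with a median log2 change of −0.16 (camera adjusted p = 3.20e-06, adjusted p = 0.262 with an estimated correlation). BOP1 fell by 0.43, the RNA polymerase I cofactor gene UBTF by 0.41 and the nucleolar protein gene GNL3 by 0.35. Of 23 YAP and TEAD targets 12 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 3.07e-06, adjusted p = 0.262 with an estimated correlation). CCN2, connective tissue growth factor, fell by 0.69, CRIM1 by 0.46 and AJUBA by 0.43. Of 29 ATF4 and CHOP targets 16 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of −0.16 (camera adjusted p = 0.000102, adjusted p = 0.262 with an estimated correlation). ASNS, asparagine synthetase, fell by 0.58 and CHAC1 by 0.49, and the lipoprotein receptor gene VLDLR rose by 0.59. Of 30 immediate early genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of −0.08 (camera adjusted p = 0.000111, adjusted p = 0.262 with an estimated correlation). The MAP kinase phosphatase genes DUSP1, DUSP4 and DUSP6 fell by 0.48, 0.41 and 0.40. Of 20 TGF-β and SMAD targets 9 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of −0.09 (camera adjusted p = 0.0263, adjusted p = 0.359 with an estimated correlation). LTBP1 fell by 0.57, and LTBP2 rose by 0.35. Of 24 epithelial genes 8 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of −0.09 (camera adjusted p = 0.0493, adjusted p = 0.607 with an estimated correlation). The keratin genes KRT19 and KRT18 fell by 0.27 and 0.26, and the claudin gene CLDN4 rose by 0.31. Of 42 ribosomal protein genes 1 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of −0.04 (camera adjusted p = 0.0401, adjusted p = 0.262 with an estimated correlation). The member that fell was RPL13, by 0.17, which was at 0.09 (limma adjusted p = 0.398) without the _x_at and _s_at probe sets and lost its call without each array but shCtrl replicate 2. The epithelial list lost its camera call without shCtrl replicate 1, shCtrl replicate 3, shMCM8 replicate 1 or shMCM8 replicate 3, the ribosomal protein list without shCtrl replicate 3 or any of the 3 shMCM8 replicates, and the TGF-β list without shCtrl replicate 3. The epithelial and ribosomal protein lists also lost it with the replicate block (camera adjusted p = 0.0795 and 0.0574), and all 3 lists under other filters or scalings. In the methods' t-test BOP1, LTBP1, LTBP2, CLDN4, KRT18, NDUFB10 and RPL13 did not pass (adjusted p from 0.0667 to 0.118). In limma's test against a 1.5-fold change, 54 genes with an adjusted p under 0.05 and a change under 2-fold did not pass. They were fixed by name or chosen as examples after the values were seen. That test asks whether a change exceeds 1.5-fold, so a gene with a smaller change could not pass it, whatever its precision. The 18S ribosomal RNA control was lower in shMCM8 by 0.24 on the log2 scale on the same arrays.

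**Figure D4:**
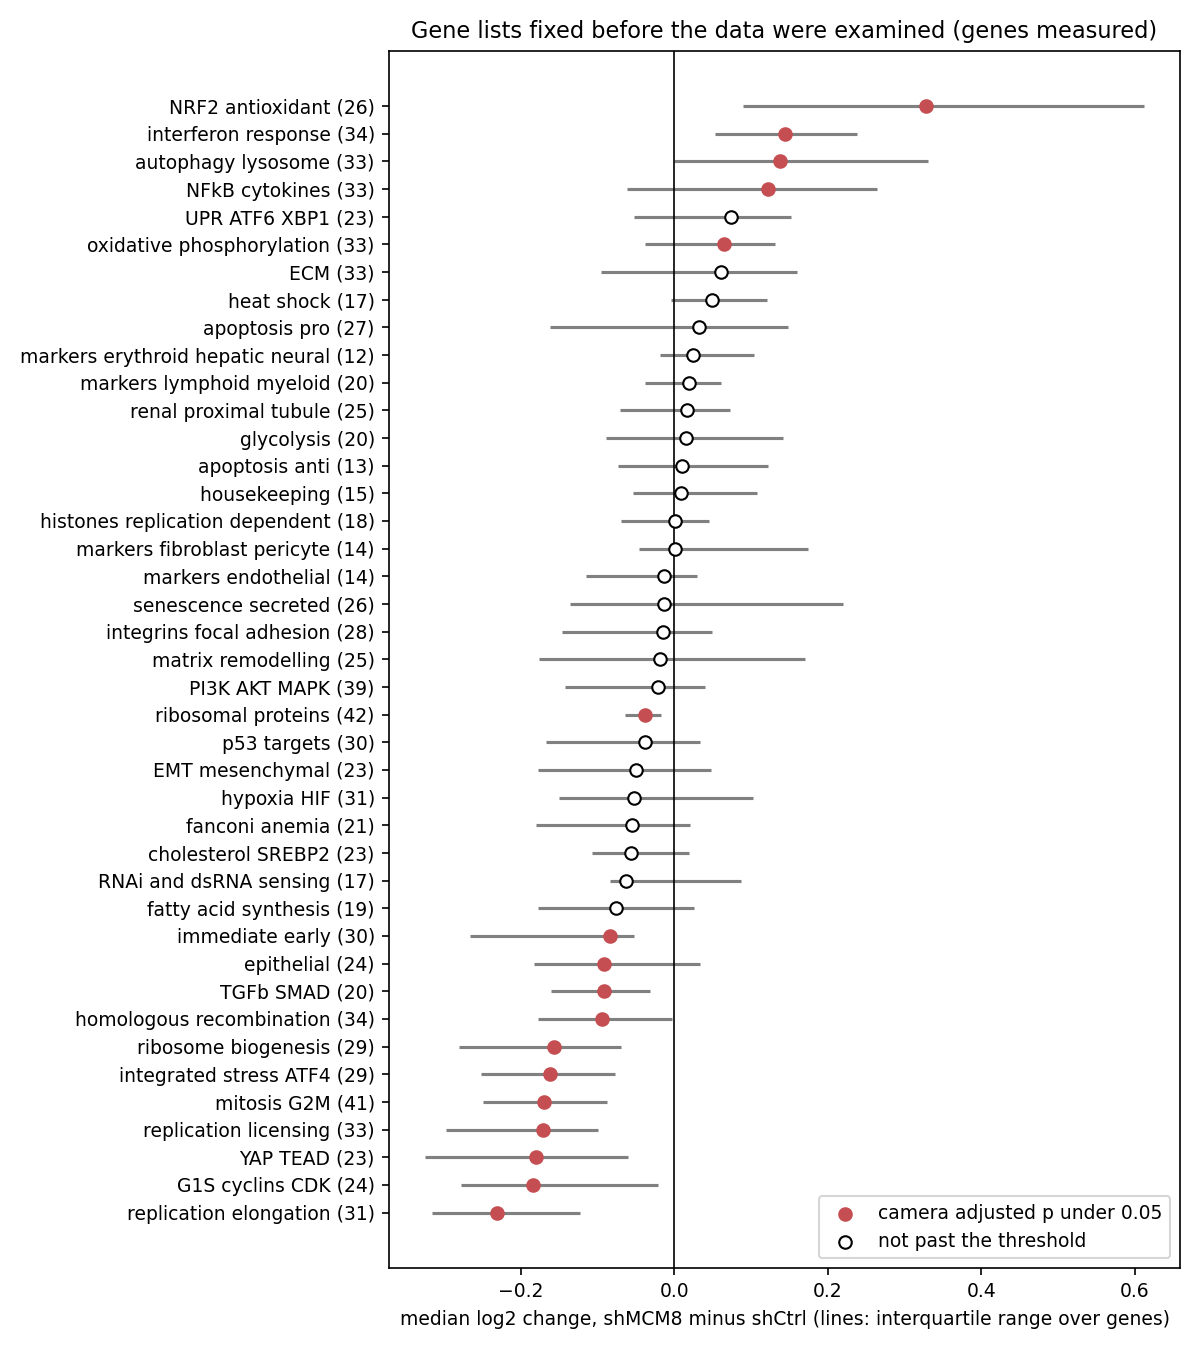
Median log2 change, shMCM8 minus shCtrl, of 41 gene lists with the number of measured genes in parentheses; lines span the interquartile range over genes and filled points passed camera's adjusted p of 0.05 with a preset correlation. The NRF2 list had the highest median (0.33) and the replication list the lowest (−0.23).

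The other 24 lists did not pass camera's threshold. Among lists of DNA damage and cell death, p53 targets had 3 rises and 7 falls in 30 genes (3 and 8 adjusted over the list alone, camera adjusted p = 0.361) and Fanconi anemia genes 2 and 7 in 21 (2 and 7 adjusted over the list alone, camera adjusted p = 0.149). Pro-apoptotic genes had 6 rises and 5 falls in 27 (7 and 6 adjusted over the list alone, camera adjusted p = 0.557), anti-apoptotic genes 3 and 2 in 13 (5 and 3, camera adjusted p = 0.557) and secreted senescence factors 8 and 6 in 26 (9 and 7, camera adjusted p = 0.557). Among stress lists, heat shock genes had 2 rises and 3 falls in 17 (3 and 3 adjusted over the list alone, camera adjusted p = 0.124), the unfolded protein response 5 and 4 in 23 (9 and 5, camera adjusted p = 0.151) and hypoxia targets 3 and 9 in 31 (5 and 9, camera adjusted p = 0.343). Among metabolic lists, glycolysis had 5 rises and 4 falls in 20 (8 and 4 adjusted over the list alone, camera adjusted p = 0.539), cholesterol synthesis 3 and 1 in 23 (3 and 3, camera adjusted p = 0.597) and fatty acid synthesis 2 and 5 in 19 (2 and 8, camera adjusted p = 0.208). Extracellular matrix genes had 9 rises and 5 falls in 33 (11 and 6 adjusted over the list alone, camera adjusted p = 0.179), matrix remodelling genes 6 and 5 in 25 (6 and 6, camera adjusted p = 0.634), mesenchymal genes 1 and 7 in 23 (1 and 7, camera adjusted p = 0.157) and integrins and focal adhesion genes 3 and 7 in 28 (3 and 8, camera adjusted p = 0.504). PI3K, AKT and MAPK pathway genes had 4 rises and 8 falls in 39 (4 and 10 adjusted over the list alone, camera adjusted p = 0.224), RNA interference and double-stranded RNA sensors 4 and 1 in 17 (4 and 1, camera adjusted p = 0.597), the histone list 2 and 2 in 18 (2 and 2, camera adjusted p = 0.843) and reference genes 2 and 1 in 15 (2 and 1, camera adjusted p = 0.454). In the histone list 1 of the falls was that of SLBP, which is not a histone. Proximal tubule markers had 1 rise and 1 fall in 25 (0 and 0 adjusted over the list alone, camera adjusted p = 0.785). Of markers of other cell types, endothelial genes had 1 rise and 1 fall in 14 (1 and 1 adjusted over the list alone, camera adjusted p = 0.597), fibroblast and pericyte genes 2 and 1 in 14 (2 and 1, camera adjusted p = 0.597), leukocyte genes 1 and 0 in 20 (1 and 0, camera adjusted p = 0.343) and red cell, hepatocyte and neural genes 2 and 0 in 12 (2 and 0, camera adjusted p = 0.195). In the last list the fibrinogen gene FGB rose by 1.15 on the log2 scale. The median and the mean or the camera direction differed in sign in the lists of senescence factors, RNA sensors, matrix remodelling and histones.

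Several kinds of control probe sets differed between the groups with no overlap of the 3 values on each side, while the 3′ probe set of ACTB and the 5′ probe set of GAPDH overlapped. The hybridization controls were higher in shMCM8 by 0.09 on the log2 scale, the poly-A spike-in controls by 0.23, and the 18S ribosomal RNA probe sets were lower, with a change of −0.24. The background probe sets changed by −0.04. The difference between the 3′ and the 5′ probe set was 0.49 ± 0.03 (SD, n = 3) in shCtrl and 0.65 ± 0.02 (SD, n = 3) in shMCM8 for ACTB, a change of 0.17, which came from the 5′ probe set (−0.165), and changed by 0.05 for GAPDH. Each of these 7 differences had an exact permutation p = 0.1, the smallest possible.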

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

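The tests of the 3 patterns below were chosen after the results were seen, and the comparison across other splits of the arrays was not. Signals outside the main comparison were these. A PSMC2 probe set not used on the gene level was higher in shMCM8 by 0.81. The poly-A spike-in controls were higher by 0.23, the 18S ribosomal RNA controls changed by −0.24 and the ACTB 3′ minus 5′ difference changed by 0.17. Among probe sets with no or several genes, 4 passed the threshold.

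The 10 splits of the 6 arrays into 3 and 3 cannot give a share under 0.05. The real split gave 44 genes against at most 0 in the others, 4139 genes at any fold against at most 0, 112 probe sets against at most 0, and 17 lists against at most 11. Only 1 of the 10 splits reached each of these real values. Up to 11 lists were called by camera with the preset correlation in splits that mix the groups. Each of these splits has 2 arrays of 1 group and 1 of the other on each side, so part of the group difference remains. Mixing also adds the group difference to the spread within each side. The counts of the other splits therefore measure no rate of false calls.

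PSMC2 fell most, with a log2 change of −2.24, while the other 26S subunits rose and MCM8 fell by 0.34. A single faulty or cross-hybridizing probe set is argued against by 2 PSMC2 probe sets that each fell by more than 1 on the log2 scale. The third PSMC2 probe set rose by 0.81 in shMCM8, and why it differed was not tested. An array-wide scaling difference shared by genes of the same level is argued against by random lists of matched level. The highest median of 10000 was 0.10, against 0.78 for the subunits. The subunit list was chosen after its values were seen and the random genes were drawn independently. That 0 of 10000 reached its median is therefore no test of the list. Whether the strongest direct effect of the hairpin was on MCM8 stays open: 465 genes fell by more than MCM8. Of these, 56 fell below the change of its lowest probe set less 2 SE of its brightest probe set. Changes downstream of MCM8 can exceed the direct one, so the count does not separate them. The other open candidate explanations are a hairpin that acted on PSMC2 RNA, through a wrong construct, a swap or an off-target match, and a change downstream of MCM8 loss. They cannot be told apart here: 10 of 64 members of the 2 replication lists fell by more than MCM8, which a fall of MCM8 as a bystander would give but a weak knockdown would too, there were 0 further groups with a second MCM8 hairpin or a rescue, and the hairpin sequence is not in the labels.

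Several control probe sets moved with the group. An array-wide intensity difference of the same size at all levels, left by the normalization, is argued against by the poly-A controls. They rose by 0.135 beyond the hybridization controls (SE 0.0174). The mean level in shCtrl was 6.87 for the poly-A and 11.66 for the hybridization controls, so a difference that depends on intensity stays open. Labelling or RNA quality that differed between the groups may contribute and stays open: the ACTB 3′ minus 5′ difference rose by 0.166, but each group was processed as 3 arrays with no batch given, so the treatment and the handling cannot be told apart.

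The replication and mitosis lists fell together. Fewer cells in S phase and mitosis could account for this, since the median of the replication list lay −0.060 (bootstrap SD over genes 0.0476) from that of the mitosis list, which does not separate them. This stays open, because no cell cycle measurement was analysed here.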

How the results depend on the processing

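All alternatives but that without _x_at and _s_at probe sets were chosen before the data were examined; the second deposited table was identical, so a comparison with it had nothing to run. Reversals were counted only for genes and lists with an adjusted p under 0.05 in 1 or both of the 2 fits. By that count 1 gene reversed: RPL13 was at 0.095 without _x_at and _s_at probe sets, and the cause was not tested. Values with no adjusted p under 0.05 in either fit could change sign, as CDKN1A did without shCtrl replicate 1 (0.035). Counts: 1249 named-gene values stayed on their side of an adjusted p of 0.05, 87 lost the call and 9 gained one, and 646 list values kept theirs, 38 lost and 8 gained. Of the 87 losses, 54 were of genes with a change under 2-fold in the test against a 1.5-fold change, which asks a different question. With the mean of all probe sets 26 genes were called, 22 higher and 4 lower. Averaging can change the value only of genes with over 1 probe set, which were 12197 of 18837. Without a fold threshold 4139 genes were called, 1900 higher and 2239 lower, by construction. In the methods' t-test 42 genes and 99 probe sets passed the threshold, 1957 genes passed at any fold, and MCM8 was at −0.34 (adjusted p = 0.143), as the per-gene variance is estimated from 3 values. In the test against a 1.5-fold change, which a smaller change cannot pass, MCM8 was at −0.34 (adjusted p = 1). With an estimated correlation 0 lists were called, and the cause was not tested. The estimated correlation of the ribosomal protein list was 0.0087, under the preset 0.01. Its unadjusted camera p still went from 0.0157 with the preset to 0.0693 with the estimate. A correlation above the preset therefore does not account for the change in that list. Leaving out 1 array gave 37 to 50 genes, 30 to 43 higher, 7 to 8 lower, 2648 to 3901 genes at any fold (lowest without shMCM8 replicate 3, and 2716 without shMCM8 replicate 2), 105 to 120 probe sets, 14 to 17 lists and an MCM8 change of −0.420 to −0.296, with fewer samples in the fit. Over the alternatives of limma other than the test against a 1.5-fold change, the adjusted p of MCM8 ranged from 0.000147 to 0.0592. With the replicate block 44 genes, 3501 genes at any fold, 112 probe sets and 15 lists were called, and MCM8 was at −0.34 (adjusted p = 0.0177). Same-numbered arrays correlated at 0.135, −0.004 and 0.024, and 1 of 3 arrays of each group correlated best with its own number. Only replicate 1 passed the 0.1 set as needed, so the numbers were not used as pairs. Quantile normalization gave 48 genes and median centring 51, with 43 of the 44 in each. Dim genes near background limit the signal, and no detection calls were in the files used here.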

Other observations

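The tests here were chosen after the values were seen. Of 14 genes listed for p97, its cofactors and ubiquitin shuttles, with NFE2L1 and DDI2 in the list, 11 rose and 0 fell, with a median log2 change of 0.38 (camera p = 2.92e-10, p = 0.00505 with an estimated correlation). VCP, which encodes p97, rose by 0.98, its cofactor genes UFD1 by 0.98 and NPLOC4 by 0.89. Of 9 proteasome assembly factors POMP rose, by 0.50, and PSMG3, PSMG4 and PSMG2 fell, by 0.18, 0.16 and 0.15. NFE2L1, a transcription factor known to act on proteasome genes, was at −0.10 (limma adjusted p = 0.125), and DDI2, a protease known to process its protein, at −0.04 (limma adjusted p = 0.559). No member of the immunoproteasome list passed (0 of 5, limma, with 1 at an unadjusted p under 0.05). PSMB8 was at 0.11 (limma adjusted p = 0.0936).

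Among Gene Ontology terms called lower, RNA splicing had 75 falls and 20 rises in 278 genes, with a median log2 change of −0.07 (camera adjusted p = 0.00884, unadjusted p = 0.293 with an estimated correlation). The centromeric region of chromosomes had 46 falls and 13 rises in 136 genes, with a median of −0.09 (camera adjusted p = 0.00612, unadjusted p = 0.227 with an estimated correlation). DNA strand elongation had 15 falls and 0 rises in 31 genes, with a median of −0.15 (camera adjusted p = 0.000224, unadjusted p = 0.158 with an estimated correlation). None of the 3 passed with an estimated correlation after adjustment.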
